A study of Homo sapiens with 2 samples.

How the data were processed

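RNA sequencing was done on total RNA of undifferentiated H9 human embryonic stem cells (hESC) and of neural precursor cells (NPC) derived from them on a feeder layer of MS5 cells. H9 is an established pluripotent human line and MS5 is a mouse stromal line used as a feeder. Per the labels' protocols, RNA was taken up in Trizol, 1.3 µg of total RNA went into each library, and libraries were made with a SMARTER mRNA-Seq kit. There was 1 library per group, so no test between conditions was possible and no p-value was computed.

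The deposited values are raw read counts per gene symbol, 1 column for each library, as whole numbers whose totals differ between the libraries. Per the submitters' processing notes, TopHat and edgeR were used with the hg19 build, with no role or order stated. The counting tool, its strand setting, its treatment of reads that map to several places and the annotation are not given in the sources used here. Without a stated strand setting, a gene cannot be told apart from an overlapping or antisense partner (EMX2 and EMX2OS, or NKX2-1, SFTA3 and NKX2-1-AS1). Read counts of near-identical copies, such as HBA1 and HBA2, POU5F1 and its pseudogenes or the NBPF family, are uncertain too. The treatment of reads that map to several places is not given. No row lacked a gene name.

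Each count file held 25737 rows in the same order. There were 286 symbols on several rows, and the row with most reads over both libraries was kept. That left 24462 symbols and set aside 0.0878% of the hESC reads and 0.107% of the NPC reads. The reference annotation in hand was of another build than hg19, so no coordinates are given.

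Library sizes were scaled with trimmed-mean-of-M-values (TMM) factors from edgeR 4.0.16 in R 4.3.3, which were 0.884 for the hESC and 1.13 for the NPC library. No label gives a library batch, and with 1 library per group a batch and the group cannot be told apart. CPM (counts scaled to the effective library size) and log2 ratios, NPC over hESC, were computed from these effective sizes, with 0.5 added to each count for the point ratio. Each ratio has an exact 95% counting interval (Clopper-Pearson on the NPC share of the reads of a gene). Genes with at least 5 CPM in either library were called measured. A measured gene was called higher or lower when the bound of its interval nearest to no change was at least 2-fold. A gene that reached 5 CPM in 1 library only could therefore not be called in the other direction. The intervals cover counting error only. They hold no variation between cultures, and reads without molecular identifiers are not independent molecules. Where a library had 0 reads, the fold is given against a floor of 3 reads in that library.

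The median log2 ratio of each of 23 gene lists was set against 10000 random lists of the same size, matched in 20 bins of mean expression, and is given with its percentile as a description of these libraries. The interval of a list's median is the exact binomial one over its members. Fixed before the data were examined were the lists, the size rule, the alternatives and the rule for named genes. That rule takes POU5F1, NANOG, SOX2, SOX1, PAX6 and NES, the 10 genes each way with the interval bound farthest from no change, up to 2 higher and 2 lower members of each list and, for a list with no called member, its most abundant one. Other genes named, such as OTX2, FEZF2, EMX1, SPON1, PAX5, TUBB3, DCX, SNAP25, VIM, CDH2, GFAP, SOX10, HOXA5 or the globins, were chosen after their values were seen. A few genes that the rule takes are not reported here.

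The ratio and interval code was tested on simulated counts without replicate variation for 24462 genes. It called 0 of 67 genes changed 1.5-fold, 66 of 67 changed 3-fold and 66 of 66 changed 8-fold, and 0 of 12658 unchanged genes. The intervals held the true value for 95.6% of unchanged genes. The changed genes were few, were drawn from well covered genes and went in both directions. The simulation therefore does not cover genes with few reads or scaling where many genes differ.

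Alternatives were the library total, DESeq2 1.42.0 size factors and upper-quartile factors in place of TMM, filters at 1 and 20 CPM or none, removal of mitochondrial and ribosomal protein genes, a 4-fold bound, the point ratio alone, log2 of CPM + 1 and, for the correlation, a pseudocount of 0.1. Added after seeing the data were the sum of all rows of a symbol and the removal of the trend with transcript length (lowess in statsmodels 0.14.6, fraction 0.5, longest transcript per symbol in GENCODE 29, found for 94.8% of measured genes). Intervals of correlations across genes come from 1000 bootstrap resamples. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.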

Results

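Gene expression was measured by RNA sequencing in 1 library of undifferentiated H9 hESC and 1 library of H9-derived NPC made by co-culture with MS5 feeder cells. The comparison asks how the transcriptome of the NPC differed from that of the line they came from. The hESC library held 19686728 counted reads and the NPC library 24065750. Reads were found for 20184 symbols in the hESC and for 21180 symbols in the NPC library. A gene at the filter of 5 CPM rested on about 86.9 reads in the hESC and 136 reads in the NPC library, and a count of 0 allows up to 0.173 CPM and 0.110 CPM. All differences below are between these 2 libraries. No replicate check exists, and the intervals are counting intervals only.

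Genes of pluripotent and epithelial cells were lower in the NPC library, and most genes of lists for neural progenitors, neurons and the forebrain were higher. The pluripotency factor gene POU5F1 was 1851-fold lower (95% interval 1204 to 3211) and the neuroectoderm factor gene PAX6 was 78.4-fold higher (50.9 to 136). All 16 measured genes of a forebrain list and all 10 of a midbrain and floor plate list were higher. Most of these genes passed the filter in the NPC library alone and could not have been called lower. Of 22 measured stroma and fibroblast genes, 14 were higher and 4 lower. In the pluripotency list 24 of 25 measured genes were lower, as were 17 of 18 in the glycolysis and hypoxia list. SOX2 and NES, which are used as neural stem cell markers, differed by less than 2-fold.

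Of 13535 measured genes, 2649 were higher and 2683 were lower in the NPC library by at least 2-fold at the near bound of the interval. The other 8203 genes did not pass the size rule. A near bound of 16-fold or more was reached by 295 higher and 260 lower genes. Log2(CPM + 1) values of the libraries correlated with Pearson's r of 0.658 and Spearman's rho of 0.687 across genes, which are not independent replicates. The split depended on scaling: 49.7% of calls were higher with TMM, against 67.2% with the library total (3679 higher, 1796 lower), which shifts every log2 ratio by 0.36. The ratios below are relative to TMM.

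**Figure D1:**
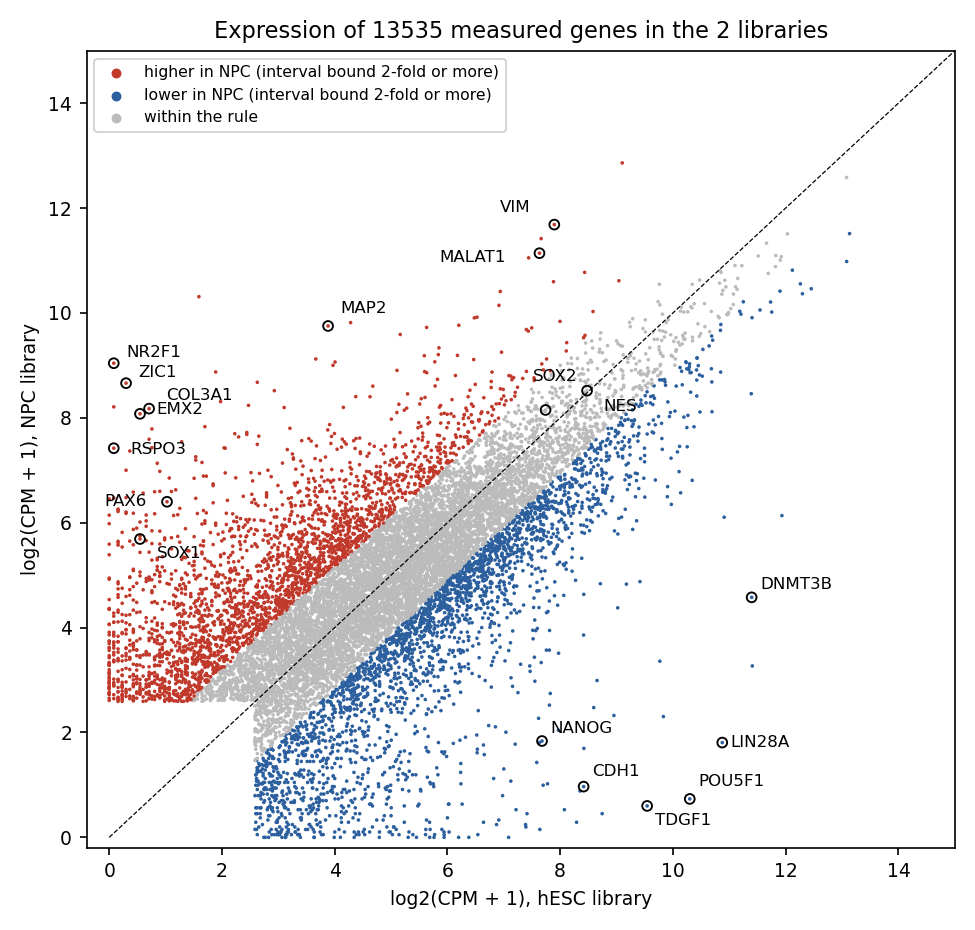
Expression of the 13535 measured genes as log2(CPM + 1) in the hESC library (horizontal) and the NPC library (vertical), 1 point per gene, with the dashed line at equal values. Red points are the 2649 genes higher in the NPC library, blue points the 2683 lower ones and grey points those within the size rule; ZIC1 and NR2F1 lie at the upper left, POU5F1 and LIN28A at the lower right, and NES near the line.

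Pluripotency genes were lower in the NPC library almost throughout. POU5F1, the core pluripotency factor OCT4, had 1259 CPM in the hESC and 0.662 CPM in the NPC library. NANOG, another core factor, was 78.6-fold lower (62.5 to 102). Of 25 measured members of the pluripotency list, 24 were lower and none was higher, with a median log2 ratio of -6.31 at percentile 0 of the matched random lists. The Nodal co-receptor TDGF1 was 1398-fold lower (862 to 2648), the RNA-binding protein gene LIN28A 746-fold lower (592 to 968) and the DNA methyltransferase gene DNMT3B 118-fold lower (109 to 128). Reads of POU5F1 can be shared with its copies, of which POU5F1B had 1050 reads in the hESC and 2 in the NPC library. SOX2, which is expressed in both pluripotent and neural stem cells, had 213 CPM in the hESC and 283 CPM in the NPC library, a ratio of 1.33 (1.28 to 1.38).

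Epithelial genes were lower as a group. In the surface ectoderm and epithelium list 11 of 12 measured members were lower and none was higher, with a median log2 ratio of -5.43 (percentile 0). The splicing factor gene ESRP1, active in epithelia, had 3450 reads in the hESC and 3 in the NPC library, a ratio of 1543 (615 to 8731). The tight junction gene CLDN6 was 585-fold lower (348 to 1179), and CDH1, the gene of E-cadherin, was 350-fold lower (243 to 546). CDH2, the gene of N-cadherin, was 11.2-fold higher (10.7 to 11.7) in the NPC library.

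The 10 genes lower by the farthest bound also held ZSCAN10, a zinc finger gene of pluripotent cells. It was at least 1223-fold lower, with 2344 hESC reads and 0 NPC reads. CYP2S1, a cytochrome P450 gene, was 1307-fold lower (650 to 3860), and the long non-coding RNA LINC00458 was 1109-fold lower (633 to 2428). LAD1 was at least 746-fold lower and LOC101929194 at least 657-fold lower. VRTN had 1600 hESC reads and 1 NPC read, a ratio of 1670 (449 to 98959).

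Neural progenitor genes were higher in the NPC library. Of 27 measured members of that list, 21 were higher and 2 lower, with a median log2 ratio of 4.75 (percentile 100). Among the higher genes, MSI1, FABP7, VIM, ZNF521, SOX9, SOX11 and CDH2 reached 5 CPM in the hESC library. The other higher genes passed the filter in the NPC library alone and could not have been called lower. PAX6 had 1.04 CPM in the hESC and 83.4 CPM in the NPC library. SOX1, an early neural marker, was 103-fold higher (55.6 to 255). The nuclear receptor gene NR2F1 had 1 read in the hESC and 14304 in the NPC library, a ratio of 6094 (1640 to 361051), and the zinc finger gene ZIC1 was 1560-fold higher (685 to 6442). VIM, the gene of vimentin, was 13.9-fold higher (13.4 to 14.3) and reached 3291 CPM. NES, the gene of the intermediate filament nestin and a common neural stem cell marker, was 355 CPM in the hESC and 366 CPM in the NPC library, a ratio of 1.03 (0.997 to 1.06). POU3F1 was 7.42-fold lower (6.11 to 9.12), and PROM1, which encodes CD133, was 4.68-fold lower (4.25 to 5.18). Genes of stroma and fibroblasts were higher in the same library (14 of 22, given with their values among the other lineages).

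Genes of neurons were also higher in most cases. Of 25 measured members of the neuron list, 18 were higher and 1 lower, with a median log2 ratio of 3.61 (percentile 100). Among the higher genes, DCX, MAP2, ELAVL3, NCAM1, GAP43 and INA reached 5 CPM in the hESC library. The other higher genes passed the filter in the NPC library alone and could not have been called lower. TUBB3, SYP, SYT1, NEFL, NEFM and CRMP1 reached 5 CPM in the hESC library and did not pass the size rule. MAP2, a dendritic microtubule protein gene, was 62.5-fold higher (55.1 to 71.4), and the stathmin gene STMN4 was 116-fold higher (65.8 to 253). DCX, a marker of migrating neuroblasts, was 9.77-fold higher (8.77 to 10.9), and SNAP25, which encodes a synaptic protein, had 8 and 348 reads, a ratio of 26.2 (14 to 64.9). TUBB3 had 213 CPM in the hESC and 196 CPM in the NPC library and did not pass the rule. RBFOX3, which encodes the mature neuron antigen NeuN, was 10.4-fold lower (7.97 to 14.1).

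The glia list split, with 3 higher and 1 lower among 8 measured members (median log2 ratio 0.27, percentile 69.6), and 3 higher and 3 lower with a filter at 1 CPM or none. S100B was 45.8-fold higher (28.1 to 87.0) and the astroglial glutamate transporter gene SLC1A3 4.61-fold higher (4.09 to 5.22), while the myelin gene MBP was 14-fold lower (10.1 to 20.5). GFAP had 35 reads in the hESC and 44 in the NPC library, below the filter in both.

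**Figure D2:**
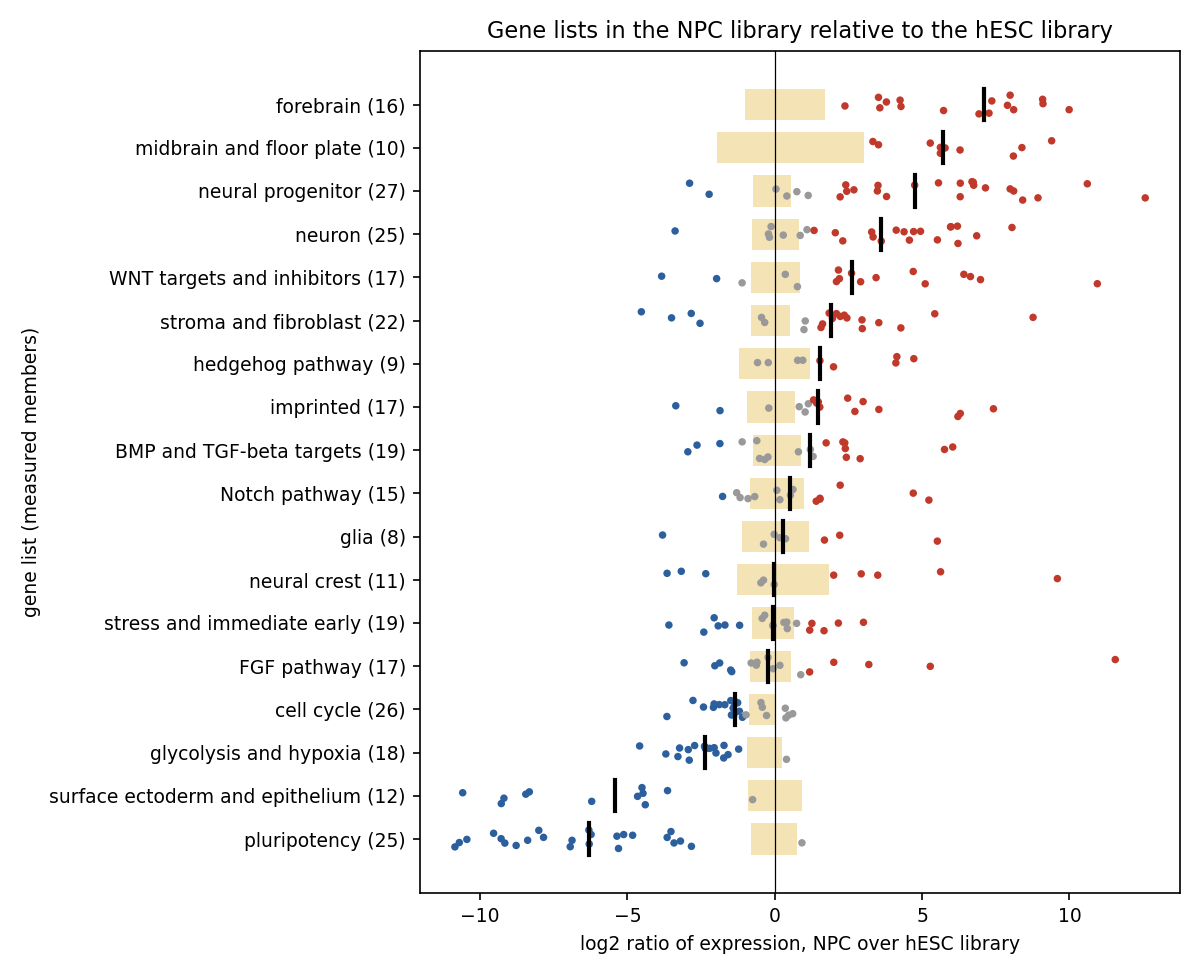
Log2 ratio of expression (NPC over hESC library, horizontal) for the measured members of each gene list with at least 6 of them, 1 point per gene, red for higher, blue for lower and grey for within the size rule. Black bars are list medians and shaded boxes hold the central 95% of the medians of 10000 matched random lists; the forebrain median of 7.10 lies farthest right and the pluripotency median of -6.31 farthest left.

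Forebrain genes were higher in the NPC library as a group. All 16 measured members of the forebrain list were higher in the NPC library (median log2 ratio 7.10, percentile 100; 6.72 with genes at 0 reads set to their bound). Of these, OTX2, FEZF1 and LMO3 reached 5 CPM in the hESC library. The others passed the filter in the NPC library alone and could not have been called lower. With a filter at 1 CPM 18 members of the list were higher and 1 lower, EMX1, with 22 and 2 reads, a ratio of 14.1 (4.23 to 151). EMX2, a dorsal telencephalic factor, was 550-fold higher (296 to 1354) and reached 269 CPM, although without a stated strand its reads cannot be told from those of its antisense partner EMX2OS (5 and 4464 reads). NKX2-1, a ventral forebrain and hypothalamic factor, had 1 read in the hESC and 2387 reads in the NPC library, a ratio of 1017 (274 to 60272), with the same limit for NKX2-1-AS1 and SFTA3. OTX2, a fore- and midbrain factor, was 13.8-fold higher (12.2 to 15.8) at 199 CPM, and FEZF2 was 238-fold higher (142 to 481) at 171 CPM. All 10 measured members of the midbrain and floor plate list were higher as well (median log2 ratio 5.70, percentile 99.99; 5.62 with genes at 0 reads set to their bound). Among these SPON1 alone reached 5 CPM in the hESC library, so the others could not have been called lower. PAX2 had 2 reads against 1310, a ratio of 335 (116 to 3460), and DMRTA2 was at least 112-fold higher. SPON1 had 366 CPM, FGF8 52.4 CPM and PAX5 21.7 CPM in the NPC library. EN1, EN2, DDC and TH, the gene of tyrosine hydroxylase, lay between 6.73 CPM (EN2) and 7.87 CPM (TH), close to the filter. LMX1A (4.26 CPM) and FOXA2 (2.21 CPM), both floor plate factors, were below it. The number of higher genes in this list depended on the filter, with 16 at 1 CPM, 17 with no filter and 4 at 20 CPM.

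Hindbrain and spinal cord genes were near the detection limit. Of 28 members of that list 27 were below the filter in both libraries. NKX6-1 was measured, with 2 reads in the hESC and 769 in the NPC library, a ratio of 197 (67.8 to 2032), and its log2 ratio of 7.62 is the list's median (percentile 99.5). With more or other members measured the median was 4.72 with the library total, 1.64 with a filter at 1 CPM and 1.12 with no filter. The 17 HOX genes in the list had 13 reads together in the hESC and 84 in the NPC library, where the highest, HOXA5, had 38 reads (1.40 CPM) and 6 had none.

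**Figure D3:**
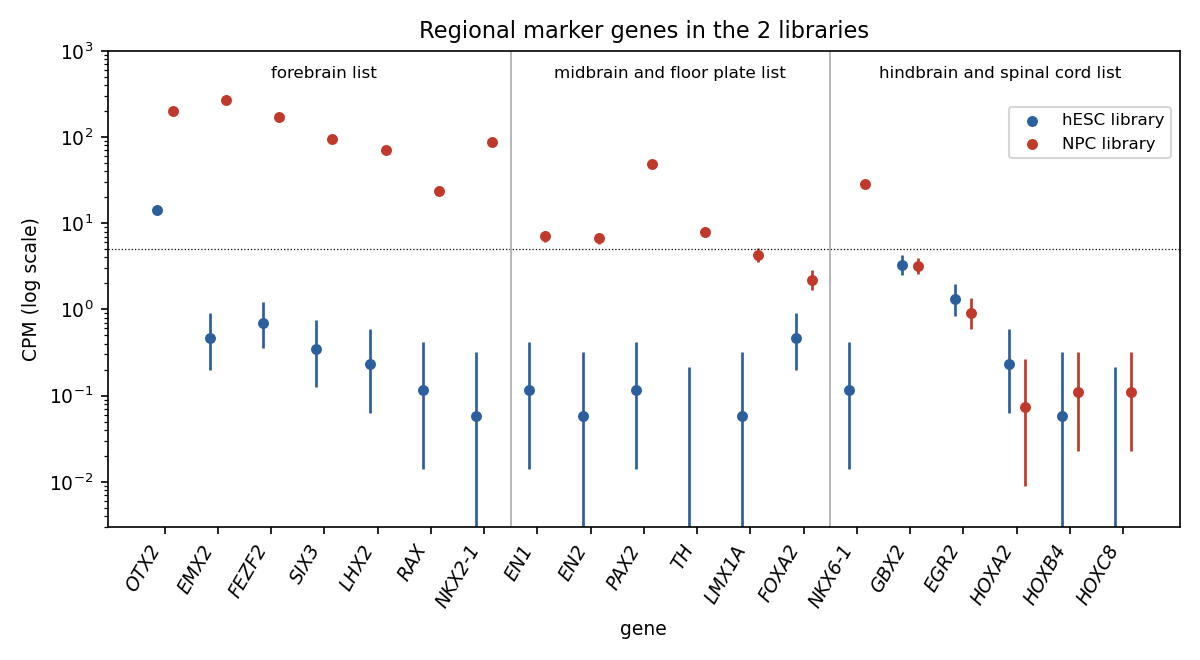
CPM on a log axis for 19 members of the regional gene lists in the hESC library (blue) and the NPC library (red); vertical bars are exact 95% Poisson counting intervals, a bar without a point is a count of 0, bars end at the lower edge of the plot, and the dotted line marks 5 CPM. In the NPC library the 7 forebrain genes shown, of which RAX is the lowest and EMX2 the highest, lie between 23.7 and 269 CPM and the 3 HOX genes shown lie below 1 CPM.

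Markers of other lineages went both ways. In the neural crest list 5 of 11 measured genes were higher and 3 lower (median log2 ratio -0.02, percentile 39.6, and 0.34 with the library total). TFAP2B was at least 128-fold higher and TFAP2A 49.4-fold higher (23.1 to 168), while the neurotrophin receptor gene NGFR was 12.6-fold lower (8.82 to 19.1) and ERBB3 9.02-fold lower (7.64 to 10.8). SOX10 had 37 and 21 reads and was below the filter. In the mesoderm list 4 of 19 genes were measured. FOXC1 was 6.2-fold higher (3.75 to 11.7), while the VEGF receptor gene KDR was 8.09-fold lower (7.35 to 8.92) and TCF15, with 2 NPC reads, had a ratio of 86.7 (29.3 to 901); the median log2 ratio was -1.87 (percentile 10.7), but 0.58 with no filter. In the endoderm list 3 of 16 were measured (median log2 ratio 4.41, percentile 94.3), and with a filter at 1 CPM the median was -1.22. These were CXCR4, 21.3-fold higher (15.3 to 31.5), TTR with 2 and 146 reads, a ratio of 37.4 (12.7 to 389), and ALB, 11.7-fold lower (7.19 to 21.2).

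Stromal genes were higher in the NPC library in most cases. Of 22 measured members of the stroma and fibroblast list, 14 were higher and 4 lower. The median log2 ratio was 1.90 (interval -0.34 to 2.96, percentile 100). COL3A1, a fibrillar collagen gene, was 435-fold higher (254 to 912) at 288 CPM, and the matrix proteoglycan gene DCN was 43.1-fold higher (18.7 to 179). FN1 was 4.68-fold higher (4.50 to 4.86). CXCL12 was 23.1-fold lower (14.9 to 39.8) and THY1 11.3-fold lower (10.4 to 12.3), and COL1A1 had 250 CPM in the hESC and 183 CPM in the NPC library. Human counts do not show how many reads came from mouse feeder cells. The neural progenitor, neuron and forebrain lists were higher in the same library.

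Genes of signalling pathways were higher in part. For WNT, 12 of 17 measured targets and inhibitors were higher and 2 lower (median log2 ratio 2.61, percentile 100). RSPO3, a WNT agonist gene, had 1 read in the hESC and 4634 in the NPC library, a ratio of 1974 (531 to 116985). The WNT effector gene LEF1 was 126-fold higher (87.3 to 199) and the feedback target AXIN2 7.54-fold higher (6.58 to 8.70). The secreted inhibitor genes SFRP2 and SFRP1 were 14.3-fold (13.2 to 15.6) and 3.93-fold (3.72 to 4.15) lower. For BMP and TGF-beta, 8 of 19 were higher and 3 lower (median log2 ratio 1.21, interval -0.61 to 2.39, percentile 99.8). With the library total 11 were higher and 3 lower (median 1.56). The same counts were found with the trend with transcript length removed (median 1.45). ID4 was 65.8-fold higher (53.0 to 83.7) and TGFB2 54.2-fold higher (37.1 to 86.6), while the connective tissue growth factor gene CTGF was 7.72-fold lower (6.96 to 8.61).

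In the hedgehog list 5 of 9 were higher and none lower (median log2 ratio 1.53, interval -0.22 to 4.14, percentile 98.9). The co-receptor gene BOC was 17.3-fold higher (14 to 21.8). In the Notch list 6 of 15 were higher and 1 lower (median log2 ratio 0.53, percentile 85.3). The target HEY1 was 37.5-fold higher (24.8 to 63.2) and the ligand gene DLL1 26.0-fold higher (16.8 to 45.3), while HEYL was 3.41-fold lower (2.35 to 5.10). The FGF list split evenly, 5 higher and 5 lower of 17 (median log2 ratio -0.23, percentile 44.7). The ligand genes FGF17, at least 502-fold higher, and FGF8, 38.8-fold higher (26.3 to 62.7), stood against the FGF response genes SPRY4, 8.44-fold lower (7.81 to 9.13), and ETV4, 4.10-fold lower (3.85 to 4.36). With the library total the FGF list had 6 higher and 3 lower genes and a median log2 ratio of 0.13, and no Notch gene was lower.

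Glycolysis genes were lower in the NPC library. Of 18 measured members of the glycolysis and hypoxia list, 17 were lower and none was higher. The median log2 ratio was -2.36 (percentile 0), against a median of -0.42 for the matched random lists. The glucose transporter gene SLC2A3 was 24.0-fold lower (22.3 to 25.9), PFKP, which encodes platelet-type phosphofructokinase, 13-fold lower (11.7 to 14.4) and LDHA, the gene of lactate dehydrogenase A, 9.39-fold lower (9.02 to 9.78). VEGFA, a hypoxia target, had 48.7 CPM and 64.1 CPM. In the cell cycle list 17 of 26 were lower and none was higher. The median log2 ratio was -1.35 (percentile 0), against -0.42 for the matched random lists. CCNE1, the gene of cyclin E1, was 12.6-fold lower (10.9 to 14.7) and the replication licensing gene MCM5 6.85-fold lower (6.39 to 7.34). MKI67, the gene of the proliferation antigen Ki-67, had 415 and 633 CPM and TOP2A 728 and 933 CPM, both within the rule. With the library total, 8 cell cycle genes were lower (median log2 ratio -0.99).

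Among the remaining lists, stress and immediate early genes went both ways, 5 higher and 6 lower of 19 (median log2 ratio -0.06, percentile 54.1, and 0.29 with the library total). EGR1 was 8.06-fold higher (6.81 to 9.66) and FOS 4.46-fold higher (3.54 to 5.77), while the glutathione-degrading enzyme gene CHAC1 was 12.1-fold lower (7.87 to 20.1) and IER3 5.31-fold lower (4.58 to 6.18). Of the naive pluripotency list 4 of 12 were measured (median log2 ratio 0.24, percentile 42.3, and -1.31 with no filter), with TFCP2L1 66.6-fold lower (28.7 to 277), TBX3 28.4-fold higher (21.0 to 40.6) and KLF5 3.27-fold higher (2.43 to 4.56).

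The other genes among the 10 with the farthest higher bound were NR2F2, LGI1, MMRN1 and SPARCL1. NR2F2, a nuclear receptor gene related to NR2F1, had 1 and 8023 reads, a ratio of 3418 (920 to 202521). SPARCL1, which encodes a secreted matrix protein of the SPARC family, was 621-fold higher (453 to 905) and reached 1269 CPM. LGI1 was at least 404-fold higher and MMRN1 at least 360.4-fold higher.

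The ratio between the libraries depended on transcript length. Across 12831 measured genes with a length, Spearman's rho was 0.205 (95% interval 0.188 to 0.222). The median log2 ratio went from -0.67 in the 10% of genes with the shortest transcripts to 0.34 in the 10% with the longest. With this trend removed, 2345 of these genes were higher and 2573 lower, of which 2184 and 2203 were also called without the correction. Genes without a length could not be corrected and drop out of these counts. A length was found for 93.1% of the genes called higher and 95.4% of those called lower without the correction. The counts are therefore not over the same genes as the main ones. Pluripotency (24 lower), forebrain (16 higher) and glycolysis (17 lower) calls had the same counts, and neural progenitor calls numbered 22 higher and 2 lower. Cell cycle calls numbered 14 lower, and in the naive pluripotency list 2 genes were lower.

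**Figure D4:**
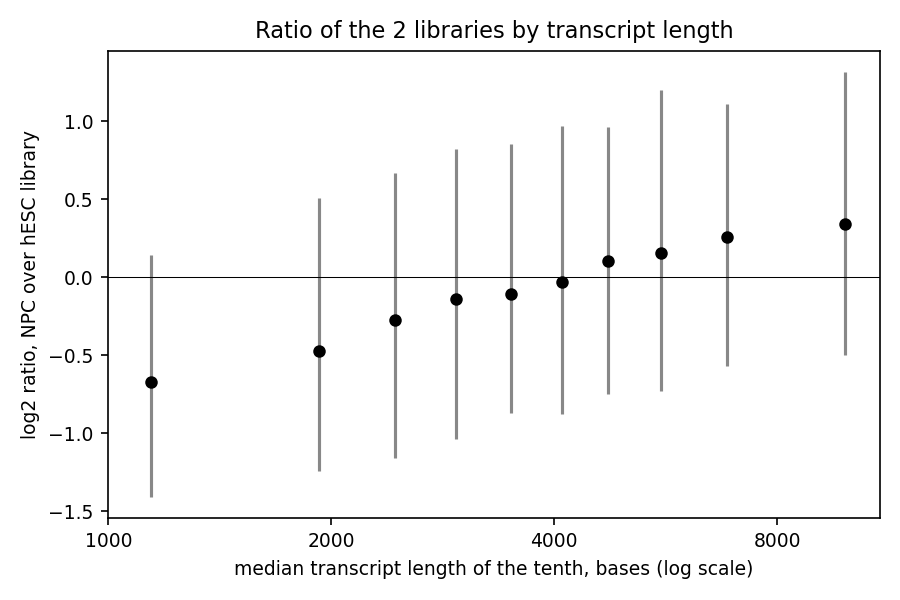
Median log2 ratio (NPC over hESC library, vertical) of the genes in each of 10 classes of transcript length against the median length of the class in bases (horizontal, log axis); bars run from the lower to the upper quartile. The medians climb from -0.67 to 0.34.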

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

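No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out and no other split of the samples could be made. The alternative pseudocount planned for normalized values was not run, since the values were counts. The length correction and the sum of rows were chosen after seeing the data. The counts of higher and lower genes stayed within 1.5 times the main counts of 2649 and 2683, except that a filter at 20 CPM gave 1684 higher genes and a 4-fold bound gave 1236 higher and 983 lower genes, both by construction. The correlation across genes was 0.780 with a filter at 1 CPM, 0.494 at 20 CPM and 0.597 with a pseudocount of 0.1. Of the recomputed list medians, 206 stayed inside the interval of the main median (or within 0.5 where under 6 members gave no interval) and 24 did not. With log2 of CPM + 1, which compresses ratios of genes near 0, the medians were -4.94 for pluripotency, 3.73 for forebrain, 3.01 for midbrain and floor plate, 4.71 for hindbrain and spinal cord, 2.51 for endoderm and -4.65 for blood and immune. The other medians that moved belong, but for 1, to lists with under 6 measured genes. Hindbrain and spinal cord moved to 4.72 with the library total, 1.64 with a filter at 1 CPM, 1.12 with no filter and 4.36 without mitochondrial and ribosomal protein genes. Mesoderm moved to -2.66 with the library total, -1.33 and -3.02 with filters at 1 and 20 CPM, and 0.58, the opposite direction, with no filter. Endoderm moved to -1.22, the opposite direction, at 1 CPM, to 0.15 with no filter and to 3.83 without mitochondrial and ribosomal protein genes. Blood and immune moved to -6.53 and -10.28 at 1 and 20 CPM, -1.13 with no filter and -9.002 with the length trend removed. Naive pluripotency moved to 4.83 at 20 CPM and to -1.31, the opposite direction, with no filter. Surface ectoderm and epithelium moved to -4.02 with no filter. These filters change which members are counted, and with them the numbers of called genes: at 20 CPM, 11 neuron genes were higher and 1 lower, 10 forebrain genes were higher and none lower, and 1 neural crest gene was higher and 2 lower, and at 1 CPM, 8 neural crest genes were higher and 5 lower, 8 hedgehog genes were higher and none lower, and 18 forebrain genes were higher and 1 lower. At 1 CPM the glia list had 3 higher and 3 lower genes, endoderm 4 and 4, hindbrain and spinal cord 3 and 0, naive pluripotency 2 and 3, and surface ectoderm and epithelium 1 and 11. With the 4-fold bound, 10 glycolysis and hypoxia genes and 4 cell cycle genes were lower and 9 stroma genes were higher and 4 lower. The hedgehog list had 3 higher genes and none lower both at 20 CPM and with the 4-fold bound. Of the recomputed ratios of the 83 named genes, 732 stayed inside their counting intervals, 97 moved and none of the called genes changed direction. A filter leaves a gene's ratio as it is, so all 83 stayed by construction at 1 CPM, at 20 CPM and with no filter. The scaling alternatives shifted log2 ratios by at most 0.36, and log2 of CPM + 1 keeps the sign. For called genes, at least 2-fold from no change, these settings could not reverse a direction. Depth limits the genes with 0 to 3 reads in a library, whose ratios are bounds or have intervals spanning more than 10-fold.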

Other observations

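Most members of the following gene families were not in the lists, which held the claudins CLDN6 and CLDN7. These families were chosen after seeing the data. Of 38 measured genes of the protocadherin family of adhesion molecules, which include the pseudogene PCDHGB8P, 25 were higher and 1 was lower in the NPC library (median log2 ratio 2.15, percentile 100 of matched random lists). All 4 genes of the NFI transcription factor family were higher (median log2 ratio 4.84), with NFIX at a log2 ratio of 6.94 and NFIA at 5.77. The Robo and Slit axon guidance genes were higher in 5 of 6 cases, led by SLIT1 (5.74) and SLIT2 (5.57) on the log2 scale. Their median was 2.38 (interval -0.57 to 5.74). Ephrins and Eph receptors split 9 higher to 3 lower of 19 (median 1.22, interval -0.57 to 2.53), and EPHA1 was the lowest at -9.98. Of 11 ionotropic glutamate receptor genes 6 were higher and none lower (median 2.55, interval -0.78 to 5.33). GABA-A receptor genes had 1 higher and 3 lower of 6 (median -0.95, interval -2.72 to 7.74, percentile 8.6), or 2 and 3 with the library total. Semaphorins split 4 higher to 4 lower of 19 (median 0.09, percentile 60.7), or 8 to 3 with the library total. Of 6 measured claudins 5 were lower (median -2.92), CLDN6 and CLDN7 among them. Ribosomal protein genes were lower in 24 of 78 cases, with none higher (median -0.93). With the library total 5 were lower (median -0.58), and with the trend with transcript length removed 13 were lower (median -0.60).

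Imprinted genes, a list fixed before the data were examined, were higher in 11 of 17 measured cases and lower in 2 (median log2 ratio 1.48, percentile 99.99). DLK1 was 171-fold higher (130 to 236) and PLAGL1 78.6-fold higher (46.7 to 159). SNRPN was 3.62-fold lower (3.51 to 3.74) and PHLDA2 10.3-fold lower (5.89 to 20.7), though PHLDA2 was below the filter with the library total, which left 1 lower gene. In the blood and immune list all 4 measured genes were lower (median log2 ratio -9.60, or -7.76 with genes at 0 reads set to their bound, percentile 0). The other 11 members were below the filter, and the median was -6.53 with a filter at 1 CPM and -1.13 with none. The adult globin genes HBA1 (710 and 1 reads, a ratio of 741, interval 199 to 43947), HBA2 (669 and 0 reads, at least 349-fold) and HBB (259 and 0 reads, at least 135-fold) were present in the hESC library, where the red cell genes ALAS2 and AHSP had 12 and 13 reads and the leukocyte gene PTPRC had 8. In a list of 8 red blood cell genes without these globins, chosen after seeing the data, 1 gene was measured. This was SLC4A1, with 59 reads in the hESC and 180 in the NPC library, 1.94-fold higher (1.45 to 2.66) and within the size rule. Interferon response genes, also chosen after seeing the data, split 5 higher to 4 lower of 14 (median 0.10, percentile 37.4), with IFI44L at 2 and 2058 reads, IFI44 at 0 and 533, ISG15 at 270 and 66 and HERC5 at 837 and 62.

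Every test of an explanation below was chosen after its pattern was seen, and no biological explanation was tested, since the cell type, the culture and the library differ together. The NBPF gene family took 0.113% of the hESC reads and 1.80% of the NPC reads, and NBPF20 was the most abundant symbol of the NPC library at 7441 CPM, 13.6-fold higher (13.3 to 13.9). Of 11 measured NBPF genes 10 were higher (median log2 ratio 3.41), and the nuclear non-coding RNA MALAT1 was 11.4-fold higher (11 to 11.8). The trend with transcript length does not account for all of it, since the median of these 12 genes was 3.46 before and 3.14 after its removal. Reads shared between NBPF copies may make 1 change appear many times. The SD of the 11 log2 ratios was 1.01, at percentile 36.5 of random sets, a value between the limits set for either answer. NBPF3 lay alone at 0.28, and the 10 higher genes lay between 2.64 (NBPF12) and 3.83 (NBPF1). The SD thus depends largely on NBPF3 and cannot decide the question. More unspliced nuclear RNA in the NPC library also stays open. A set of 6 other non-coding RNAs taken as nuclear (KCNQ1OT1 is also in the imprinted list) had a median log2 ratio of 0.97. With 6 members its interval, -0.84 to 2.92, runs from the lowest value to the highest. OIP5-AS1, at -0.84, was the only member with a negative ratio. Where these RNAs lie in these cells was not measured, so the set cannot decide the question.

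Small nucleolar RNAs (snoRNA) can lie in introns of host genes. The 101 snoRNA entries that were paired with such a host had ratios close to those of their hosts. Over 63 host genes the log2 ratios of snoRNA and host correlated with Pearson's r of 0.985 across genes, and the count of SNORD35A was 20.5% of that of its host RPL13A in the hESC and 20.4% in the NPC library. Of 132 measured snoRNA entries, with or without a paired host, 3 were higher and 47 lower, and the source of their reads was not tested.

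The trend with transcript length held when genomic span was taken into account, with a partial Spearman's rho of 0.139 (interval 0.122 to 0.157), so that long genomic spans of neural genes do not account for all of it. Among 591 genes of general cell machinery, such as proteasome, splicing and mitochondrial genes picked by symbol, rho was 0.260 (interval 0.189 to 0.328). This is consistent with a yield of RNA or library that depends on length, although a difference in these genes between the cell types would look alike. With 1 library per group the group and the library cannot be separated.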
